A study of Mus musculus with 2 samples.

How the data were processed

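Single-cell RNA-seq was available from subcutaneous A20 tumours of BALB/c mice, 1 library from an animal or animals given TAK-981 and 1 from the vehicle arm. Per the labels' protocols, 1000000 A20 cells were inoculated per mouse, dosing began at a tumour volume of about 300 mm3, and mice received intravenous TAK-981 at 7.5 mg/kg or a vehicle of 20% hydroxypropyl-type cyclodextrin. Tumours were taken after 8 h, dispersed mechanically through a 70 µm filter, depleted of dead cells, and loaded on the 10x Genomics Chromium 5' kit to target about 3000 droplets with cells. The deposited files give, per library, whole-number counts of UMIs per gene and barcode, not normalized, per the file headers. Per the submitters' processing notes, Cell Ranger 2.1.1 and Seurat 2 were used, with no role given. The genome build and annotation are not given in the sources used here, so genes are named by the identifiers and symbols of the files and no coordinates are given. The lowest UMI total per barcode was 4670 in the TAK-981 and 5965 in the vehicle library, so barcodes had been selected before deposit. The number of mice behind each library is not stated in the labels used here. Genes with near-identical copies, such as Ifit3 and Ifit3b, Tgtp1 and Tgtp2, the H2-Q genes, Ly6c1 and Ly6c2 and the histone genes, are uncertain one by one, since the authors' counting could split or lose their reads.

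All further steps were computed from the counts in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-image 0.26.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests, gene lists, cell type markers, filters, rule for named genes and first set of alternatives were fixed before the data were examined. Cells were kept with at least 200 genes detected and under 10% of UMIs from mitochondrial genes, which removed 8 and 376 barcodes of the TAK-981 library and 6 and 124 of the vehicle library. Scrublet, run per library at its automatic threshold, marked 2 cells (0.0994%) and 1 cell (0.0408%), which were removed. At these loadings more doublets are to be assumed, so this step in effect left them in, and T cell-like and monocyte/macrophage-like cells with B cell/A20 transcripts were counted and left out in an alternative. Counts were scaled to 10000 per cell and log-transformed. From both libraries together, without integration, 2000 variable genes were chosen after leaving out mitochondrial, ribosomal protein, immunoglobulin and T cell receptor variable genes and the interferon, GTPase, MHC class I and chemokine lists, so that these genes did not set the clusters. Other genes that respond may still have done so. With 30 principal components, 15 neighbours and Leiden resolution 1.0 (seed 0), 15 clusters were found.

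Clusters were named from markers fixed for 13 cell classes. The scoring was set after the clusters were seen: a class needed at least 3 of its markers among the 50 genes with the highest fold over other cells (with 0.1 added per 10000). A cluster with none was called B cell/A20-like where at least 3 B cell markers were detected in 10% or more of its cells, since these cells are the bulk against which the others stand out. A cluster with more markers of another class among its 10 leading genes stayed unnamed, which kept 9.90% and 13.03% of cells out of the B cell/A20-like class. Host B cells and A20 cells share these markers and were not separated.

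With 1 library per arm there is no test across conditions, and no p-value or number of changed genes was computed. Within each class with at least 30 cells in both libraries, UMIs were summed over cells and divided by the class sum (scaled to CPM). The log2 ratio of TAK-981 over vehicle carries the exact conditional binomial 95% interval. Against 0 UMIs it is a bound from a floor of 3 counts over the class sum. For 30 gene lists, 1 value per class, of which those described were chosen after all values had been seen, the median was taken over members with at least 10 UMIs in both libraries together, with an interval from 1000 Poisson redraws of the counts and its percentile among 10000 random lists of equal size. Random genes were drawn from 100 neighbours in UMI number. This matching was first done on CPM and was changed after the list results had been seen once, because simulated unchanged lists had come out off centre in T cell-like cells. The redraw interval is pulled towards 0 where counts are low, so none is given for thinned values. Genes at least 2-fold higher or lower are described by size only. Shares of cells carry exact (Clopper-Pearson) intervals, and a share of 0 is given the limit of 3 cells of the total. For shares and UMIs per cell, each cell was thinned without replacement to 1000 UMIs, and no cell was shallower. Intervals and floors cover counting error only, not differences between mice. Those of ratios and list medians take each UMI as independent and leave out variation between cells. They are therefore too narrow where few cells hold most UMIs of a gene.

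Named genes were, per class, the 10 with the highest and the 10 with the lowest bound nearest to no change among genes with at least 30 UMIs in the higher library, without immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes. Added to these were up to 4 members per described list with the largest absolute ratio at 30 UMIs or more, genes of the SUMO pathway, of which Sumo2, Sumo3, Sae1 and Uba2 are given, and Ifnb1, the Ifna genes, Ifng, Cd69 and Cxcl10. Other genes named are cell type markers.

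The calculation was tested on simulated class sums, drawn as Poisson counts from the real class means. The intervals assume this same model, so their coverage below was largely set in advance. Variation between cells was not simulated, and coverage of the real counts is not shown. Intervals held the true value for 94 to 98% of genes changed 2-fold or 4-fold up or down in T cell-like cells (7871 genes), 94 to 100% in monocyte/macrophage-like cells (6861 genes) and 92 to 98% in B cell/A20-like cells (12118 genes). The interval of a 2-fold higher gene lay above no change for 82%, 70% and 98% of such genes, and that of a 2-fold lower gene below it for 62%, 66% and 94%. Lists of 40 genes raised 4-fold reached percentile 100 in all 100 simulations of each class. Unchanged lists had median percentiles of 41.4, 48.8 and 51.3, so a percentile in T cell-like cells is still slightly low.

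The alternatives were mitochondrial limits of 5% and 20%, at least 500 genes per cell, no doublet removal, interferon genes among the clustering genes, Leiden resolutions 0.5 and 2.0, classes given to each cell from markers (with at least 2 marker UMIs), median-of-ratios scaling, totals without immunoglobulin, mitochondrial and ribosomal protein genes, no minimum or a minimum of 50 UMIs per gene, a mean over cells, thinned cells, and thinning to 500 or 2000 UMIs. Added after the data were seen were the omission of T cell-like and monocyte/macrophage-like cells with at least 5, or at least 10, UMIs of B cell/A20 markers, Jchain and Mzb1, of T cell-like cells with an NK marker UMI, of monocyte/macrophage-like cells with a C1q or Siglech UMI and of the 1% of B cell/A20-like cells richest in interferon-list UMIs, and the inclusion of the unnamed cluster. In the per-cell marker classes, plasma cell calls were counted as B cell/A20-like, also a choice made later.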

Results

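The 2 libraries held single-cell RNA counts from subcutaneous tumours of the A20 line, a B cell lymphoma line of BALB/c mice, grown in BALB/c hosts. Tumours were taken 8 h after 1 intravenous dose of TAK-981 at 7.5 mg/kg or of its cyclodextrin vehicle. TAK-981 inhibits the enzyme that activates SUMO, a small protein that cells attach to other proteins, many of them regulators of transcription. There was 1 library per arm and therefore no replicate, so no test between the arms was possible, and all intervals below cover counting error only. The TAK-981 library held 2396 barcodes with 37470319 unique molecular identifiers (UMIs), a median of 11840.5 per barcode. The vehicle library held 2579 barcodes with 57471750 UMIs and a median of 19608. Mitochondrial transcripts made up 10% or more of the UMIs in 376 TAK-981 barcodes (15.7%, exact binomial 95% interval 14.3 to 17.2%) and in 124 vehicle barcodes (4.81%, 4.01 to 5.71%), and these were left out. After filtering, 2010 cells of the TAK-981 library and 2448 of the vehicle library were compared.

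Most cells of both tumours were B cell/A20-like, with Cd79a, a chain of the B cell receptor complex, in 91.7% of them in the TAK-981 library and 94.1% in the vehicle library. This class held 1716 cells (85.4%, 83.8 to 86.9%) of the TAK-981 library and 2022 cells (82.6%, 81.0 to 84.1%) of the vehicle library, in 12 clusters. T cell-like cells, marked by the CD3 chains Cd3d, Cd3e and Cd3g of the T cell receptor complex, numbered 49 (2.44%, 1.81 to 3.21%) and 60 (2.45%, 1.88 to 3.14%). Monocyte/macrophage-like cells, marked by lysozyme (Lyz2) and Cd14, numbered 46 (2.29%, 1.68 to 3.04%) and 47 (1.92%, 1.41 to 2.55%). The shares of the T cell-like and the monocyte/macrophage-like classes differed between the libraries by less than their counting intervals. A further cluster, led by Hmox1 and Xbp1, stayed unnamed and held 199 cells (9.90%) and 319 cells (13.03%). With this cluster counted as B cell/A20-like, the share of that class was no longer larger in the TAK-981 library. The female X-inactivation transcript Xist was found in 44 of 49 and 56 of 60 T cell-like cells, 37 of 46 and 42 of 47 monocyte/macrophage-like cells, and 6 of 1716 and 20 of 2022 B cell/A20-like cells. Among lineage genes in other classes, Lyz2 was seen in 0 of 49 and 0 of 60 T cell-like cells (which allows shares of up to 6.12% and 5%), and Cd3e in 0.291% and 0.396% of B cell/A20-like cells. Transcripts of the B cell/A20-like class were found more often in host cells: Mzb1 in 24.5% and 28.3%, Jchain in 20.4% and 23.3% and Cd79a in 18.4% and 20% of T cell-like cells, and Jchain in 17.4% and 14.9% and Mzb1 in 13.04% and 21.3% of monocyte/macrophage-like cells. Median UMIs per cell were 6698 and 9349.5 in T cell-like, 8378 and 10453 in monocyte/macrophage-like and 14181.5 and 20190.5 in B cell/A20-like cells.

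The first comparison asked in which cells of the tumour interferon-stimulated genes differed 8 h after TAK-981. Genes of the type I interferon response were higher in the TAK-981 library in all 3 cell classes, with a median of 11.1-fold in monocyte/macrophage-like, 7.51-fold in T cell-like and 3.16-fold in B cell/A20-like cells. On the log2 scale the medians were 3.47 (counting interval 3.17 to 3.64, 55 genes measured), 2.91 (2.65 to 3.18, 47 genes) and 1.66 (1.48 to 1.91, 45 genes). At least 2-fold higher values were found for 51 of 55, 46 of 47 and 36 of 45 of these genes, and none was 2-fold lower in any class. Each median lay above all 10000 random lists of genes matched on UMI number, a description of these 2 libraries. Gene by gene, the log2 ratio was larger in monocyte/macrophage-like than in B cell/A20-like cells by a median of 1.24 (1.01 to 1.59) and larger in T cell-like than in B cell/A20-like cells by 1.02 (0.71 to 1.23). Monocyte/macrophage-like cells exceeded T cell-like cells by 0.39 (0.08 to 0.70). With each cell thinned to 1000 UMIs the medians were 3.16, 2.29 and 1.13.

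In monocyte/macrophage-like cells antiviral genes with almost no UMIs in the vehicle library had the highest ratios. Ifit1 (ENSMUSG00000034459), which binds viral RNA, had 316 UMIs against 0 and was at least 136-fold higher. Rsad2 (ENSMUSG00000020641), which encodes viperin, an enzyme that makes an antiviral nucleotide, had 656 UMIs against 3, a ratio of 282 (96.0 to 1370). Ifit2 had 284 against 2 (ratio 183, 50.2 to 1519), the nucleotide kinase Cmpk2 180 against 1 (232, 41.1 to 9214), and Ifit3 164 against 1 (211, 37.4 to 8399). The T cell-attracting chemokine Cxcl10 (ENSMUSG00000034855) had 1140 against 34 and was 43.2-fold higher (30.7 to 62.7). Mx1, a dynamin-like antiviral GTPase, had 151 against 2, and Usp18, a protease that restrains interferon receptor signalling, 167 against 3. Ifit3b had 53 against 0, at least 22.8-fold higher, and Slfn4 had 77 against 1. Among the guanylate-binding proteins and immunity-related GTPases, which attack vacuoles that hold pathogens, 12 of 13 were at least 2-fold higher (median log2 ratio 2.85, 2.40 to 3.19). Gbp5 was 14.2-fold higher (5.16 to 54.3) and Ifi47 10.6-fold higher (7.60 to 15.1).

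In T cell-like cells genes of the same list with high ratios were Ifit1, with 99 UMIs against 2 (ratio 104, 27.9 to 868), and the ubiquitin-like modifier Isg15 (ENSMUSG00000035692), with 398 against 19, 43.9-fold higher (27.7 to 73.6). Rsad2 had 51 UMIs against 0 and was at least 35.6-fold higher, and Ifit3 had 33 against 0, at least 23.03-fold higher. Rtp4 had 51 UMIs against 2, Usp18 37 against 3, and the exonuclease gene Isg20 was 11.5-fold higher (7.16 to 19.2). Of the guanylate-binding proteins and immunity-related GTPases, 13 of 14 were at least 2-fold higher (median log2 ratio 2.08, 1.90 to 2.51), among them Irgm1 at 18.3-fold (6.55 to 71.0), Gbp9 at 8.57-fold (4.36 to 18.4) and Gbp2 at 8.18-fold (5.01 to 13.9). B cell/A20 transcripts were present in part of this class: 10 of 49 TAK-981 and 12 of 60 vehicle cells held 5 or more UMIs of B cell/A20 markers, Jchain and Mzb1, and 5 of 49 (10.2%) and 12 of 60 (20%) held 10 or more. Without the cells that held 5 or more, the interferon median was 2.61 and the GTPase median 1.79.

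B cell/A20-like cells also held more of these transcripts in the TAK-981 library, with a smaller median ratio than the host cells. Mx1 (ENSMUSG00000000386) had 113 UMIs against 1 (ratio 178, 31.3 to 7089), Ifit3 120 against 2 (94.5, 25.6 to 789), Rtp4 159 against 5 (50.1, 21.0 to 156) and Ifit1 127 against 7 (28.6, 13.5 to 72.5). Ifit3b, a near copy of Ifit3, had 55 against 1. Usp18 was 12.4-fold higher (10.3 to 14.9), Isg15 10.9-fold (9.45 to 12.7) and Oasl1 9.40-fold (6.44 to 14.1). Outside the list, the homeobox gene Prrxl1 had 42 UMIs against 0, at least 22.04-fold higher, and Dao, which encodes an oxidase of D-amino acids, 60 against 7. Of the guanylate-binding proteins and immunity-related GTPases, 11 of 15 were at least 2-fold higher (median log2 ratio 1.28, 1.15 to 1.46), led by Ifi47 (5.86-fold, 4.88 to 7.08) and Irgm1 (5.69-fold, 4.49 to 7.26). Over the 11 clusters of this class with at least 30 cells in both libraries, the interferon median ranged from 0.16 to 1.94.

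Per cell, after thinning to 1000 UMIs, which no cell fell short of, the median number of interferon-list UMIs was 28 in the TAK-981 and 5 in the vehicle library for monocyte/macrophage-like cells, 8 and 2 for T cell-like cells and 1 and 0 for B cell/A20-like cells. At least 1 such UMI was found in 95.7% (85.2 to 99.5%) and 93.6% (82.5 to 98.7%) of monocyte/macrophage-like cells, 95.9% (86.0 to 99.5%) and 80.0% (67.7 to 89.2%) of T cell-like cells, and 55.7% (53.3 to 58.0%) and 44.8% (42.6 to 47.0%) of B cell/A20-like cells. Unthinned, 100% of both host classes and 97.8% and 98.3% of B cell/A20-like cells held one, so that this share was saturated. Isg15 alone separated the libraries further. Thinned, it was found in 76.1% (61.2 to 87.4%) against 21.3% (10.7 to 35.7%) of monocyte/macrophage-like cells, 42.9% (28.8 to 57.8%) against 1.67% (0.0422 to 8.94%) of T cell-like cells and 3.67% (2.83 to 4.67%) against 0.544% (0.272 to 0.971%) of B cell/A20-like cells. Unthinned, these shares were 91.3% and 40.4%, 75.5% and 18.3%, and 18.7% and 7.72%. None of the 3 classes lacks Isg15, so its free-RNA share could be bounded only by the lowest of these values, in B cell/A20-like cells.

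**Figure D1:**
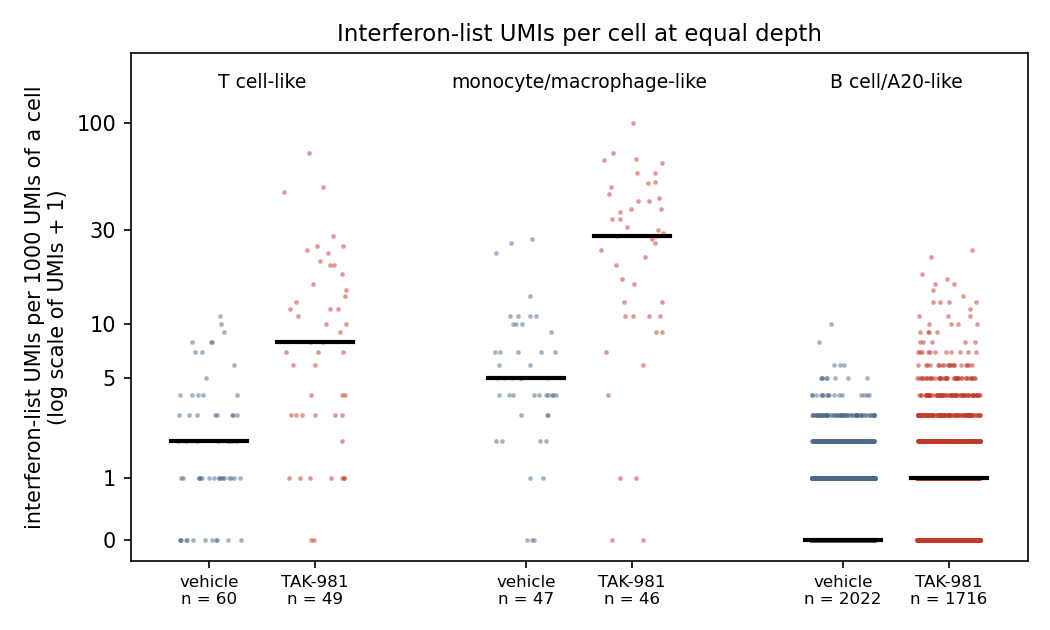
Interferon-list UMIs per cell after thinning each cell to 1000 UMIs, by cell class and library, with 1 point per cell and a line at the median. The medians were 28 (TAK-981) and 5 (vehicle) in monocyte/macrophage-like, 8 and 2 in T cell-like and 1 and 0 in B cell/A20-like cells.

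The type I interferon genes themselves were at or near 0 UMIs at this depth. Ifnb1 and the Ifna genes had 0 UMIs in every class of both libraries, except for 1 Ifna13 UMI in vehicle B cell/A20-like cells. Ifng, the type II interferon, had 11 UMIs in TAK-981 and 32 in vehicle T cell-like cells (log2 ratio -0.47, -1.61 to 0.55). The type I interferon receptor chains lay between 2-fold lower and 2-fold higher in all 3 classes, with Ifnar1 at -0.85 (-1.64 to -0.10) in monocyte/macrophage-like, 0.17 (-0.53 to 0.83) in T cell-like and 0.75 (0.58 to 0.91) in B cell/A20-like cells. Feedback regulators of the response were higher in each class (medians 1.37, 1.76 and 0.38), with 5 of 8, 5 of 8 and 2 of 10 at least 2-fold higher. This list shares Usp18 and Isg15 with the interferon list, and these are the 2 genes in B cell/A20-like cells. After thinning the T cell-like median was 3.19 and the B cell/A20-like median 0.89, and that of monocyte/macrophage-like cells 2.11 without cells that held 5 or more B cell/A20 UMIs. These values cover only genes that kept at least 10 UMIs, which can favour genes high in the TAK-981 library. Besides Usp18 and Isg15, Socs1, which inhibits the JAK kinases, had log2 ratios of 1.53 (0.83 to 2.27), 1.77 (1.00 to 2.56) and 0.93 (0.75 to 1.11). For the activation marker Cd69 the log2 ratio was -0.14 (-0.56 to 0.26) in T cell-like, 1.77 (1.01 to 2.59) in monocyte/macrophage-like and -0.20 (-0.38 to -0.02) in B cell/A20-like cells.

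Genes of the inhibited pathway lay on both sides of 0. The SUMO pathway list had medians of 0.05 (-0.13 to 0.25) in T cell-like, 0.22 (-0.20 to 0.37) in monocyte/macrophage-like and 0.11 (0.05 to 0.16) in B cell/A20-like cells, of which the last was 0.04 under median-of-ratios scaling. At least 2-fold higher were 2 of 20, 3 of 21 and 1 of 22 of its genes, and at least 2-fold lower 0, 2 and 0. Sae1 and Uba2, the 2 subunits of the enzyme TAK-981 inhibits, had log2 ratios of -0.09 (-0.15 to -0.03) and -0.23 (-0.28 to -0.18) in B cell/A20-like cells, the class with most UMIs. There Sumo2, at 0.05 (0.02 to 0.07), turned to -0.02 under that scaling. Sumo3 (ENSMUSG00000020265) was higher, 1.43-fold (1.37 to 1.49) in B cell/A20-like cells and 3.14-fold (1.90 to 5.34, 56 UMIs against 23) in monocyte/macrophage-like cells, and at 0.08 (-0.50 to 0.65) in T cell-like cells. Pml, a component of SUMO-rich nuclear bodies and itself interferon-inducible, was 2.57-fold higher (2.19 to 3.02) in B cell/A20-like cells.

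The second comparison asked which other gene groups differed in the T cells of the tumour. T cell-like cells of the TAK-981 library held more transcripts of cytotoxic effectors: 7 of 11 measured genes were at least 2-fold higher and none 2-fold lower (median log2 ratio 1.84, 1.56 to 2.08). Granzyme B (Gzmb, ENSMUSG00000015437) was 10.5-fold higher (7.99 to 14.0, in 22 of 49 cells against 13 of 60), Fas ligand (Fasl) 6.42-fold (3.52 to 12.4), perforin (Prf1) 5.41-fold (3.33 to 9.06) and Gzma 5.01-fold (4.17 to 6.05). Few cells carried some of these UMIs: Gzma was found in 9 of 49 cells against 5 of 60 and Prf1 in 14 against 9, and 1 vehicle cell held 55.8% of the vehicle library's Gzma UMIs. Gzma and Gzmb were also among the 10 leading genes of this cluster. An NK marker UMI was present in 11 of 49 and 10 of 60 cells, and without these cells the cytotoxicity median was 2.17. Thinned, it was 1.29. Inhibitory receptors had a median of 0.61 (0.36 to 0.90), with 1 of 8 at least 2-fold higher, and Pdcd1, which encodes PD-1, at 0.78 (0.47 to 1.10). This median was 0.27 without the cells that held B cell/A20 UMIs and -0.44 after thinning, the latter over only the genes that kept at least 10 UMIs. A CD8 marker UMI was found in 24 of 49 and 36 of 60 cells, and a CD4 marker UMI in 14 of 49 and 19 of 60.

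Of 6 measured inflammatory cytokines and chemokines, 5 were at least 2-fold higher in T cell-like cells of the TAK-981 library (median log2 ratio 2.62, 2.22 to 3.72, and 3.91 for genes with at least 50 UMIs). The chemokines Ccl4, with 271 UMIs against 12, and Ccl3, with 74 against 7, had the highest ratios, 47.3 and 22.1, but 1 cell held 98.9% of the TAK-981 library's Ccl4 UMIs and 98.6% of its Ccl3 UMIs. Without cells that held an NK marker UMI the log2 ratio of Ccl4 was -1.69. Cxcl10 was 10.3-fold higher (5.13 to 22.7) and Ccl5, a chemokine of effector T cells, 3.57-fold higher (3.18 to 4.02). Genes of MHC class I and its peptide supply were higher by a median of 0.73 (0.63 to 0.81), with 18 of 19 above 0 and 3 at least 2-fold, among them H2-T22 at 2.43-fold (1.94 to 3.04) and the peptide-loading chaperone Tapbp at 2.22-fold (1.74 to 2.82). The list of monocyte genes, several of which effector T cells also express, was higher too (median 1.92, 1.47 to 2.23, 5 measured, and 1.07 after thinning), with Plac8 at 2.63 (1.85 to 3.46) and Ly6c2 at 1.92 (1.49 to 2.37). Genes of the G1/S phase of the cell cycle were lower, with 17 of 18 below 0 and 6 at least 2-fold lower (median -0.68, -0.90 to -0.46, and -0.34 without cells that held an NK marker UMI). Cyclin E1 (Ccne1) had 5 UMIs against 38 and the uracil glycosylase Ung 7 against 52. Genes of G2/M had a median of 0.44 (0.26 to 0.67), with 18 of 20 above 0.

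The 10 lowest genes of T cell-like cells included several that the B cell/A20-like class expressed strongly. MHC class II had 5 of 8 genes at least 2-fold lower (median -1.21, -1.56 to -0.91), with H2-Ab1 3.39-fold lower (2.54 to 4.61), H2-Aa 3.13-fold (2.47 to 4.02) and the invariant chain Cd74 2.63-fold (2.33 to 2.97). B cell receptor and identity genes had a median of -0.69 (-1.09 to -0.33). Without the T cell-like cells that held 5 or more B cell/A20 UMIs, the medians were -0.67 for MHC class II and 0.04 for the B cell genes, and at a limit of 10 UMIs -0.05 and 0.12. The limit of 10 left out the same 12 vehicle cells but 5 instead of 10 TAK-981 cells. Cells with fewer than 10 but at least 5 such UMIs thus stayed in the TAK-981 library only, which raises these ratios. Without the cells that held 5 or more, Rhox5 (38 UMIs against 288) went from -1.86 to 1.15, and the immunoglobulin joining chain Jchain (60 against 367) from -1.55 to -0.26, and to 1.59 at the limit of 10 UMIs. The other low genes stayed lower: Dapl1 (24 against 187) at -1.90 (-2.57 to -1.28) and -2.42 without those cells, Bmyc (12 against 102) at -2.02 (-3.02 to -1.15) and -2.04, the tetraspanin Cd81 (24 against 169) at -1.75 (-2.43 to -1.13) and -1.54, and the mitochondrial protease Htra2 (2 against 35) at -3.06 (-6.16 to -1.10) and -3.79. Chst1, a sulfotransferase gene, had 0 UMIs against 30, at least 4.78-fold lower.

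The third comparison asked the same of the myeloid cells. Monocyte/macrophage-like cells of the TAK-981 library held more transcripts of genes listed for blood monocytes, fewer of tissue macrophages and fewer of MHC class II. Of 10 monocyte genes, 7 were at least 2-fold higher and all 10 above 0 (median log2 ratio 1.49, 1.35 to 1.59): the chitinase-like Chil3 was 4.85-fold higher (3.55 to 6.74), Ly6c1 3.05-fold (2.44 to 3.83), and the coagulation factor gene F13a1 2.97-fold (2.37 to 3.73). Another member, Ccr2, had 160 UMIs against 176 before scaling, in 76.1% and 83.0% of cells. The list was also higher in T cell-like cells (1.92), so it does not mark monocytes alone. Of 12 genes of tissue macrophages and alternative activation, 10 were at least 2-fold lower (median -2.18, -3.15 to -1.59). The complement genes C1qa (ENSMUSG00000036887), C1qb and C1qc had 0 UMIs against 100, 104 and 93, at least 25.9-fold, 26.9-fold and 24.1-fold lower. These vehicle UMIs came from 7 cells for each gene, and in all 8 of 47 vehicle cells and 0 of 46 TAK-981 cells held a C1q UMI, the latter allowing up to 6.52%. The mannose receptor Mrc1 had 2 UMIs against 60 (log2 ratio -4.54, -7.62 to -2.63) and the complement receptor C3ar1 2 against 65 (-4.66, -7.73 to -2.75). The remaining lowest genes were Ccl8 (0 against 56, from 1 cell), Gm15056 (0 against 47), Ecm1 (5 against 77), the uridine phosphorylase Upp1 (2 against 45) and the transcriptional inhibitor Id2 (36 against 275). Of 9 MHC class II genes, 6 were at least 2-fold lower (median -1.10, -1.79 to -0.97). H2-Aa (ENSMUSG00000036594) was 3.61-fold lower (3.36 to 3.87), Cd74 3.55-fold (3.40 to 3.72), H2-Eb1 3.48-fold (3.17 to 3.83) and H2-Ab1 3.31-fold (3.04 to 3.61).

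Without cells that held a C1q UMI or one of Siglech, a plasmacytoid dendritic cell gene (2 of 46 and 4 of 47 cells), the MHC class II median was -1.89 and the tissue macrophage median -0.26. Without cells that held 5 or more B cell/A20 UMIs (4 of 46 and 8 of 47) they were -1.76 and -4.42. Thinned, they were -1.84 and -0.59.

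**Figure D2:**
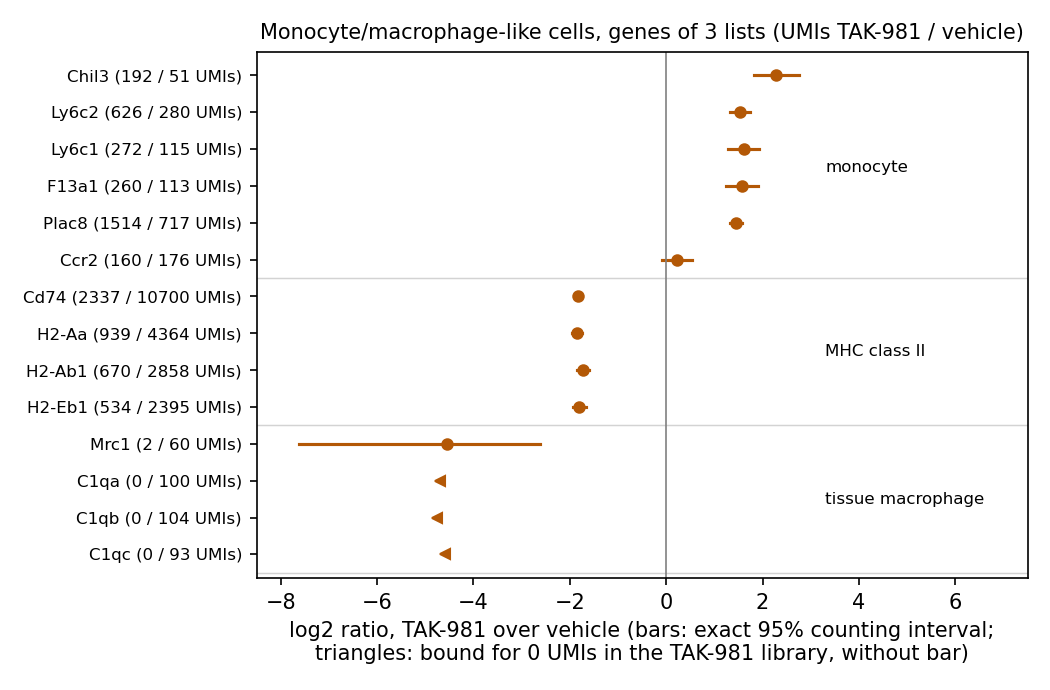
Log2 ratio of TAK-981 over vehicle in 46 and 47 monocyte/macrophage-like cells for genes of the monocyte, MHC class II and tissue macrophage lists, chosen after their values were seen, with UMIs of both libraries beside each name. Points with bars give the ratio and its exact 95% counting interval, and triangles the bound for 0 UMIs; Chil3 lies at 2.28, H2-Aa at -1.85 and C1qa at -4.69 or lower.

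Cytokine and chemokine genes split within this class, with 7 of 19 at least 2-fold higher and 8 at least 2-fold lower (median -0.61, -0.79 to -0.31). Beside Cxcl10, Ccl5 had 136 UMIs against 12 (14.6-fold higher, 8.10 to 29.0, in 6 and 4 cells) and Il15, a growth factor of T and NK cells, 44 against 4 (14.2-fold, 5.16 to 54.3). The median was -0.11 without cells that held a C1q or Siglech UMI and 0.03 after thinning. Of the genes associated with type II interferon, 3 of 11 were at least 2-fold higher (median 0.40, 0.04 to 0.64, and 0.87 after thinning), including Cxcl9 at 5.41-fold (3.63 to 8.28), while Irf8, a transcription factor of the myeloid lineage, was 2.29-fold lower (1.76 to 3.01). MHC class I genes had a median of 0.30 (0.23 to 0.60), with 3 of 19 at least 2-fold higher. All 16 genes of hypoxia and glycolysis were below 0 and 5 at least 2-fold lower (median -0.78, -0.96 to -0.64), with Ndrg1 at 3.02-fold lower (2.103 to 4.44) and the phosphofructokinase Pfkl at 2.67-fold (1.51 to 4.99).

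The last comparison concerned the tumour cells. In B cell/A20-like cells no list with at least 5 measured genes had a median 2-fold higher or lower, apart from the interferon and GTPase lists, although single genes did. Lists with lower medians in the TAK-981 library included immediate early genes, T cell activation, G1/S and MHC class II, and, nearer to 0, heat shock (-0.15, -0.16 to -0.14), G2/M (-0.12, -0.15 to -0.06) and hypoxia (-0.08, -0.10 to -0.04). The immediate early list had a median of -0.23 (-0.29 to -0.14, 9 of 15 below 0), with the AP-1 factor Fos (ENSMUSG00000021250) 2.36-fold lower (2.24 to 2.49), Ier2 1.66-fold (1.55 to 1.78) and the phosphatase Dusp1 1.64-fold (1.46 to 1.85). This list was drawn up for genes of tissue dissociation as well. With 1 library per arm, differences in tumour dispersal cannot be told apart from the treatment. Of 18 genes of G1/S, 17 were below 0 and none 2-fold lower (median -0.26, -0.29 to -0.22), with the helicase subunit Mcm6 1.36-fold lower (1.31 to 1.40). Clusters shifted both ways between the libraries: those led by Hist1h1b (cluster 2) and by Ung and Cdc6 (cluster 7) held 9.40% and 5.37% of TAK-981 cells against 13.4% and 7.43% of vehicle cells, and cluster 6, led by Gm26917 and Kcnq1ot1, 11.4% against 4.70%. Median UMIs per cell in cluster 6 were 7945 and 10166, below the 14181.5 and 20190.5 of the whole class. Whether barcode quality underlies its larger share was not tested. Cluster 9, led by Hist1h2ae, held 5.47% against 3.55% and cluster 3, led by Mki67, 11.5% against 9.23%. Cluster 0, led by Ube2c and Plk1, was lower, at 10.70% against 14.38%. Cluster 4, led by Ube2c and Ccnb1, was also lower, at 6.92% against 10.66%. The clusters not listed here lay on both sides as well. Genes of MHC class I had a median of 0.32 (0.30 to 0.35), with their transactivator Nlrc5 2.25-fold higher (1.85 to 2.73) and H2-Q7 2.02-fold (1.81 to 2.25). MHC class II had a median of -0.19 (-0.24 to -0.15), with Cd74 at 1.11-fold lower (1.10 to 1.11). Genes of T cell activation, which include Nr4a1 and Egr2, had a median of -0.45 (-0.65 to -0.13). Among the 10 lowest genes were also Ppm1n (3 UMIs against 39), Gm26802 (103 against 522), the AP-1 factor Fosl1 (16 against 87), the annexin Anxa10 (312 against 1004), the transcription factor Cebpb (874 against 2470), Cblc (51 against 180), the protease Klk4 (1449 against 3892) and Arl5c (1190 against 3169). Ccl5 (9 against 50) was at -1.82 (-3.03 to -0.78), but at 2.09 with a mitochondrial limit of 5%, at 1.56 with 20% and at 1.21 with coarser clusters. The median log2 ratio of all genes of this class was 0.07.

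**Figure D3:**
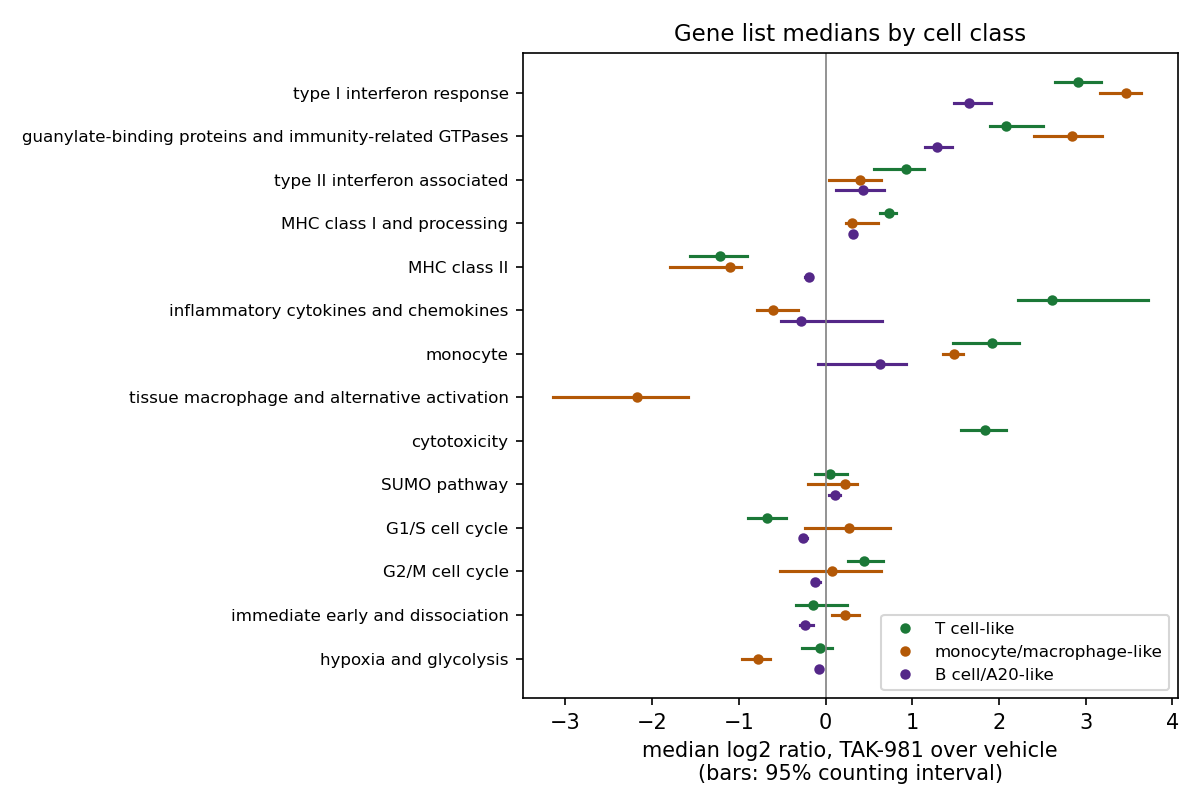
Median log2 ratio of TAK-981 over vehicle for the gene lists named on the axis, leaving out classes with fewer than 5 measured members, with bars for the 95% counting interval from redrawn counts and a line at 0. The interferon list lies at 3.47 in monocyte/macrophage-like, 2.91 in T cell-like and 1.66 in B cell/A20-like cells, and most other lists lie nearer to 0.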

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

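Among lists with at least 5 measured genes in both classes, the medians of 6 lay above 0 in 1 cell class and below 0 in another, each with a counting interval that excluded 0. None of these differences between classes was tested, since there was 1 library per arm, and the alternatives beside them that leave out cells were chosen after the data were seen.

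Inflammatory cytokines and chemokines had a median log2 ratio of 2.62 in T cell-like and -0.61 in monocyte/macrophage-like cells, 3.22 apart. The T cell-like value rests on 6 measured genes, among them Ccl4 and Ccl3 with nearly all TAK-981 UMIs in 1 cell, and the monocyte/macrophage-like value was 0.031 after thinning. Genes of the unfolded protein and integrated stress response were at 0.14 in B cell/A20-like and -0.51 in monocyte/macrophage-like cells, 0.65 apart. Genes of G2/M were at 0.44 in T cell-like and -0.12 in B cell/A20-like cells, 0.57 apart. Cholesterol synthesis was at 0.13 in B cell/A20-like and -0.37 in T cell-like cells, 0.50 apart, but the latter was 0.43 without the cells that held 5 or more B cell/A20 UMIs and 0.56 after thinning. Immediate early genes were at 0.22 in monocyte/macrophage-like and -0.23 in B cell/A20-like cells, 0.45 apart, and the former was -0.07 without the cells that held B cell/A20 UMIs. Nuclear genes of oxidative phosphorylation were at 0.04 in B cell/A20-like and -0.09 in T cell-like cells, 0.14 apart, and the former was -0.02 under median-of-ratios scaling. The T cell-like value lay at percentile 43.2 of the random lists, whose median was -0.074. It therefore did not stand apart from other genes of like UMI number.

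The barcodes with a mitochondrial share of 10% or more, which entered the comparisons only in part, through the alternative limit of 20%, also held more interferon-list UMIs in the TAK-981 library. Over 376 TAK-981 and 124 vehicle barcodes the list median was 0.91 (counting interval 0.67 to 1.24), with 14 of 31 measured genes at least 2-fold higher. Isg15 had 47 UMIs against 1, a log2 ratio of 4.29 (1.74 to 9.63). Median UMIs per barcode were 5801 and 7486.5, and these values were not split by cell class.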

How the results depend on the processing

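The tests chosen only after the data were seen were the omission of cells with B cell/A20, NK marker, C1q or Siglech UMIs, the omission of the 1% of B cell/A20-like cells richest in interferon-list UMIs, and the inclusion of the unnamed cluster. The recomputed values came to 2965, for 206 results under 23 settings. The 58 list medians among them are those described or plotted, a choice made after the settings had been run for every list. Of the list medians, 814 stayed within their counting interval, 140 left it and 12 with an interval that excluded 0 changed sign. For single genes these numbers were 1742, 171 and 12, of the shares of cells 39 stayed and 29 left their interval, and all 6 values of the differences between classes stayed. Single-gene values that left their interval without changing sign are not listed one by one. No paired analysis was possible because there was 1 library per arm, with no test to repeat.

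The interferon median stayed above 0 in every setting run, between 2.29 and 3.02 in T cell-like, 3.16 and 3.50 in monocyte/macrophage-like and 1.13 and 1.97 in B cell/A20-like cells. The GTPase median also stayed above 0, between 1.79 and 2.25, 2.69 and 3.303, and 1.21 and 1.59. Cytotoxicity in T cell-like cells lay between 1.29 and 2.17. In monocyte/macrophage-like cells the monocyte list lay between 1.27 and 1.52, MHC class II between -1.89 and -1.06 and the tissue macrophage list between -4.42 and -0.26. List medians that left their interval, and genes that changed sign, are given below with the reported value in parentheses. Shares of cells that left their interval are given without it. The word "reversed" is used where the reported interval excluded 0.

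With a mitochondrial limit of 5%, values in T cell-like cells were -0.89 for MHC class II (from -1.21). Those in monocyte/macrophage-like cells were 2.01 for interferon feedback (from 1.37). For B cell/A20-like cells they were 0.29 for MHC class I (from 0.32), -0.13 for heat shock (from -0.15) and reversed to 2.09 for Ccl5 (from -1.82). The share of B cell/A20-like cells was 74.1% in the TAK-981 library and 72.6% in the vehicle library. With a mitochondrial limit of 20%, values in B cell/A20-like cells were -0.027 for apoptosis (from 0.083), -0.30 for immediate early (from -0.23), -0.12 for hypoxia (from -0.077), 0.19 for cholesterol (from 0.13) and reversed to 1.56 for Ccl5 (from -1.82). The B cell/A20-like share was 95.8% in the TAK-981 library and 95.6% in the vehicle library. With at least 500 genes per cell, values in T cell-like cells were -0.88 for MHC class II (from -1.21). Values in monocyte/macrophage-like cells were -0.84 for cytokines (from -0.61). With doublets kept, values in T cell-like cells were -0.88 for MHC class II (from -1.21). The share of B cell/A20-like cells was 80.5% in the TAK-981 library and 77.1% in the vehicle library. With interferon genes in the clustering, values in monocyte/macrophage-like cells were -0.84 for cytokines (from -0.61). Those in B cell/A20-like cells were 1.97 for interferon response (from 1.66). The B cell/A20-like share was 87.8% in the TAK-981 library. At Leiden resolution 0.5, values in T cell-like cells were -1.59 for MHC class II (from -1.21). For monocyte/macrophage-like cells they were -0.84 for cytokines (from -0.61). Values in B cell/A20-like cells were 0.71 for cytokines (from -0.28), -0.13 for heat shock (from -0.15), -0.11 for hypoxia (from -0.077) and reversed to 1.21 for Ccl5 (from -1.82). The share of B cell/A20-like cells was 95.4% in the TAK-981 library and 95.6% in the vehicle library. At Leiden resolution 2.0, values in B cell/A20-like cells were -0.13 for heat shock (from -0.15). The B cell/A20-like share was 91% in the TAK-981 library and 87.7% in the vehicle library. With classes from markers per cell, values in T cell-like cells were 0.55 for type II interferon (from 0.93), 2.15 for cytokines (from 2.62), -0.61 for MHC class II (from -1.21), -0.056 for cholesterol (from -0.37), -0.24 for B cell identity (from -0.69) and reversed to -2.13 for Ccl4 (from 5.56). Further values in these cells were reversed, to -0.35 for Ccl3 (from 4.47). Those in monocyte/macrophage-like cells were -0.50 for NF-kB targets (from -0.32), -1.81 for MHC class II (from -1.102), -4.34 for tissue macrophage (from -2.18), 0.41 for SUMO pathway (from 0.22), 1.16 for G1/S (from 0.28) and 0.72 for G2/M (from 0.074). Others in the same class were reversed, to -0.11 for immediate early (from 0.22). For B cell/A20-like cells they were 0.69 for cytokines (from -0.28), -0.13 for heat shock (from -0.15) and -0.11 for hypoxia (from -0.077). The share of B cell/A20-like cells was 95.2% in the TAK-981 library and 95.7% in the vehicle library.

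Under median-of-ratios scaling, values in B cell/A20-like cells were 0.25 for MHC class I (from 0.32), -0.26 for MHC class II (from -0.19), 0.039 for SUMO pathway (from 0.11), -0.33 for G1/S (from -0.26), -0.19 for G2/M (from -0.12) and 0.072 for unfolded protein response (from 0.14). The same cells also gave -0.22 for heat shock (from -0.15), -0.30 for immediate early (from -0.23), -0.15 for hypoxia (from -0.077), 0.057 for cholesterol (from 0.13), reversed to -0.024 for oxidative phosphorylation (from 0.045) and reversed to -0.022 for Sumo2 (from 0.047). With totals free of immunoglobulin, mitochondrial and ribosomal genes, values in T cell-like cells were -0.19 for oxidative phosphorylation (from -0.095). With no UMI minimum, values in B cell/A20-like cells were -0.19 for heat shock (from -0.15). With a minimum of 50 UMIs, values in T cell-like cells were 3.91 for cytokines (from 2.62). As a mean over cells, values in T cell-like cells were 0.62 for MHC class I (from 0.73), -0.35 for MHC class II (from -1.21), 1.45 for cytotoxicity (from 1.84), 0.067 for inhibitory receptors (from 0.61), 1.38 for monocyte (from 1.92) and -0.25 for B cell identity (from -0.69). Values in monocyte/macrophage-like cells were 3.303 for GTPases (from 2.85), -1.89 for MHC class II (from -1.102), 1.33 for monocyte (from 1.49) and -0.54 for G2/M (from 0.074). Those in B cell/A20-like cells were 0.41 for MHC class I (from 0.32), -0.088 for monocyte (from 0.63), 0.18 for SUMO pathway (from 0.11), -0.054 for G2/M (from -0.12), -0.20 for heat shock (from -0.15) and -0.013 for hypoxia (from -0.077). Beside these, the class had 0.17 for cholesterol (from 0.13) and 0.0038 for oxidative phosphorylation (from 0.045).

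With cells thinned to 1000 UMIs, values in T cell-like cells were 2.29 for interferon response (from 2.91), 1.88 for GTPases (from 2.08), 0.50 for MHC class I (from 0.73), -0.61 for MHC class II (from -1.21), 1.29 for cytotoxicity (from 1.84) and reversed to -0.44 for inhibitory receptors (from 0.61). Further values in these cells were 1.07 for monocyte (from 1.92), -0.19 for SUMO pathway (from 0.050), 0.67 for G2/M (from 0.44), -0.12 for heat shock (from -0.36), -0.54 for hypoxia (from -0.064) and reversed to 0.56 for cholesterol (from -0.37). Others in the same class were -0.23 for oxidative phosphorylation (from -0.095), reversed to 0.070 for B cell identity (from -0.69), 3.19 for interferon feedback (from 1.76) and reversed to -0.11 for Sumo2 (from 0.19). For monocyte/macrophage-like cells they were 3.16 for interferon response (from 3.47), 3.201 for GTPases (from 2.85), 0.87 for type II interferon (from 0.40), 1.31 for nucleic acid sensing (from 0.59), reversed to 0.031 for cytokines (from -0.61) and -0.047 for NF-kB targets (from -0.32). The same cells also gave -1.84 for MHC class II (from -1.102), 2.38 for costimulation (from -0.30), 1.27 for monocyte (from 1.49), -0.59 for tissue macrophage (from -2.18), 0.45 for SUMO pathway (from 0.22) and -0.55 for G1/S (from 0.28). Beside these, the class had -0.22 for unfolded protein response (from -0.51), 0.46 for immediate early (from 0.22) and -0.52 for hypoxia (from -0.78). Values in B cell/A20-like cells were 1.13 for interferon response (from 1.66), 1.59 for GTPases (from 1.28), 0.41 for MHC class I (from 0.32), 0.35 for apoptosis (from 0.083), 0.35 for unfolded protein response (from 0.14) and -0.20 for heat shock (from -0.15). Further values in these cells were -0.36 for immediate early (from -0.23), 0.18 for cholesterol (from 0.13), 0.013 for oxidative phosphorylation (from 0.045) and 0.89 for interferon feedback (from 0.38).

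Without cells that held 5 or more B cell/A20 UMIs, values in T cell-like cells were 2.61 for interferon response (from 2.91), 1.79 for GTPases (from 2.08), 0.62 for MHC class I (from 0.73), -0.67 for MHC class II (from -1.21), 1.504 for cytotoxicity (from 1.84) and 0.27 for inhibitory receptors (from 0.61). Others in the same class were 1.42 for monocyte (from 1.92), reversed to 0.43 for cholesterol (from -0.37), reversed to 0.040 for B cell identity (from -0.69) and reversed to 1.15 for Rhox5 (from -1.86). Those in monocyte/macrophage-like cells were -0.45 for NF-kB targets (from -0.32), -4.42 for tissue macrophage (from -2.18), 1.46 for G1/S (from 0.28), 1.69 for G2/M (from 0.074), 1.23 for apoptosis (from 0.57) and reversed to -0.065 for immediate early (from 0.22). The same cells also gave -1.08 for hypoxia (from -0.78) and 2.11 for interferon feedback (from 1.37). Without cells that held 10 or more B cell/A20 UMIs, values in T cell-like cells were 2.59 for interferon response (from 2.91), 1.81 for GTPases (from 2.08), 0.61 for MHC class I (from 0.73), -0.050 for MHC class II (from -1.21), 1.45 for cytotoxicity (from 1.84) and 0.17 for inhibitory receptors (from 0.61). Beside these, the class had 1.41 for monocyte (from 1.92), reversed to 0.40 for cholesterol (from -0.37), reversed to 0.12 for B cell identity (from -0.69), reversed to 2.92 for Rhox5 (from -1.86), reversed to 1.59 for Jchain (from -1.55) and reversed to 1.92 for H2-DMb2 (from -1.03). For monocyte/macrophage-like cells they were -0.45 for NF-kB targets (from -0.32), -4.304 for tissue macrophage (from -2.18), 1.57 for G1/S (from 0.28), 1.51 for G2/M (from 0.074), reversed to -0.092 for immediate early (from 0.22) and -1.01 for hypoxia (from -0.78).

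Leaving out cells with an NK marker UMI, values in T cell-like cells were 0.42 for type II interferon (from 0.93), -1.57 for MHC class II (from -1.21), 2.17 for cytotoxicity (from 1.84), -0.34 for G1/S (from -0.68), -1.19 for B cell identity (from -0.69) and reversed to -1.69 for Ccl4 (from 5.56). Leaving out cells with a C1q or Siglech UMI, values in monocyte/macrophage-like cells were -0.11 for cytokines (from -0.61), -0.49 for NF-kB targets (from -0.32), -1.89 for MHC class II (from -1.102), -0.26 for tissue macrophage (from -2.18) and -0.64 for hypoxia (from -0.78). With the unnamed cluster included, values in B cell/A20-like cells were -0.13 for heat shock (from -0.15) and -0.11 for hypoxia (from -0.077). The B cell/A20-like share was 95.3% in the TAK-981 library and 95.6% in the vehicle library. Without the 1% of cells richest in interferon-list UMIs in each library, values in B cell/A20-like cells were 1.46 for interferon response (from 1.66) and 0.29 for MHC class I (from 0.32).

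Thinned to 500 UMIs, an interferon-list UMI was found in 83.7% (TAK-981) and 60% (vehicle) of T cell-like cells and 39% (TAK-981) and 26.1% (vehicle) of B cell/A20-like cells. Unthinned, an interferon-list UMI was found in 100% (TAK-981) and 100% (vehicle) of T cell-like cells, 100% (TAK-981) and 100% (vehicle) of monocyte/macrophage-like cells and 97.8% (TAK-981) and 98.3% (vehicle) of B cell/A20-like cells. Thinned to 2000 UMIs, an interferon-list UMI was found in 91.7% (vehicle) of T cell-like cells, 100% (vehicle) of monocyte/macrophage-like cells and 74.6% (TAK-981) and 64.2% (vehicle) of B cell/A20-like cells.

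No cluster stayed unnamed at the 20% limit and at resolution 0.5, and classes from markers per cell use no clusters. Scaling moves every gene of a class by 1 factor, by construction. At the limit of 10 B cell/A20 UMIs, cells with fewer than 10 but at least 5 stayed in 1 library only. This was the TAK-981 library for T cell-like and the vehicle library for monocyte/macrophage-like cells. Thinned medians rest on fewer genes, 17 and 34 interferon members in T cell-like and monocyte/macrophage-like cells against 47 and 55, and depth limits them. Where cells were thinned or left out, each list median was retaken over members that still had at least 10 UMIs. No minimum number of members was set, so such values can move because other genes remain. For the other values that moved or reversed, the cause was not tested.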

Other observations

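Monocyte/macrophage-like cells of the TAK-981 library also held more transcripts of proteins that sense nucleic acids, while apoptosis regulators went both ways. Of 12 measured genes of nucleic acid sensing, 11 were above 0 and 5 at least 2-fold higher (median log2 ratio 0.59, counting interval 0.28 to 1.29). Samhd1, a nucleotide hydrolase that restricts viruses, was 2.99-fold higher (2.58 to 3.49) and the adaptor gene Myd88 2.35-fold (1.76 to 3.17). Among 14 apoptosis regulators 6 were at least 2-fold higher and 3 at least 2-fold lower (median 0.57, 0.07 to 1.09). Casp4 was 5.10-fold higher (3.16 to 8.55) and Casp1, which matures interleukin-1 beta, 3.20-fold (2.05 to 5.11), while the survival gene Bcl2l1 was 2.33-fold lower (1.15 to 5.11). Of the costimulatory and checkpoint ligands, galectin-9 (Lgals9) was 6.61-fold higher (4.94 to 8.99) and Cd40 3.25-fold (2.32 to 4.602), in a list with a median of -0.30 (-0.69 to 0.24). Other lists were lower in the same cells: the p53 list at -0.39 (-0.77 to -0.10), with Gadd45b 2.28-fold lower (1.83 to 2.86), NF-kB targets at -0.32 (-0.44 to -0.13), and the unfolded protein response at -0.51 (-0.72 to -0.25), with Herpud1 1.87-fold lower (1.27 to 2.79). After thinning, the medians were 1.31 for nucleic acid sensing, 2.38 for the ligands, -0.047 for NF-kB targets and -0.22 for the unfolded protein response, and without cells that held B cell/A20 UMIs apoptosis regulators were at 1.23. These medians cover only genes that kept at least 10 UMIs, whose number is not given here. The ligand list held 531 and 331 UMIs over 9 genes before thinning, so its thinned value may rest on few genes.

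In T cell-like cells heat shock genes had a median of -0.36 (-0.47 to -0.19), with the mitochondrial chaperone Hspd1 1.63-fold lower (1.33 to 2.003) and a thinned median of -0.12. B cell/A20-like cells had a median of 0.14 (0.11 to 0.22) for the unfolded protein response, which was 0.072 under median-of-ratios scaling and 0.35 after thinning. In that list Chac1, which degrades glutathione, was 1.68-fold higher (1.49 to 1.90) and the chaperone calreticulin (Calr) 1.52-fold (1.49 to 1.56). Apoptosis regulators in B cell/A20-like cells lay near 0 (median 0.08, -0.02 to 0.19, and 0.35 after thinning), except that Bcl2l11, which encodes the death-promoting protein Bim, was 2.12-fold higher (2.02 to 2.22).

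Of the tests below, those on the myeloid lists and on the few B cell/A20-like cells rich in interferon transcripts were chosen only after the result was seen. The same holds for leaving out cells with NK, C1q or Siglech UMIs in the first pattern.

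The first pattern is the higher interferon list in T cell-like and monocyte/macrophage-like cells of the TAK-981 library. The thinned median kept at least 0.788 of the unthinned one in both classes, but this cannot decide on unequal depth per cell. It rests on the 17 and 34 members with at least 10 UMIs after thinning, which can favour genes high in the TAK-981 library. Without that limit, thinned cells held medians of 28 against 5 list UMIs in monocyte/macrophage-like and 8 against 2 in T cell-like cells. These values argue against unequal depth as the whole cause. Free RNA adds like amounts to every droplet, but the excess of list UMIs per cell over vehicle was 196 in monocyte/macrophage-like, 54.1 in T cell-like and 7.004 in B cell/A20-like cells, a ratio of 28.1 between the highest and the lowest. A different mix of subsets cannot be told apart, because no sub-cluster had 30 cells in both libraries; without cells that held NK, C1q or Siglech UMIs the lower of the medians was 0.979 of that of its class. A response to TAK-981 may account for the pattern and stays open as untested, as do differences between mice, since each arm is 1 library.

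The second pattern is the lower MHC class II and tissue macrophage lists and the higher monocyte list in monocyte/macrophage-like cells. Fewer C1q macrophages and plasmacytoid dendritic cells do not account for the MHC class II part, because its median was -1.89 (-2.001 to -1.78) without those cells against -1.10 in the whole class. A20 transcripts in vehicle droplets do not account for it either, with -1.76 (-1.85 to -1.65) without cells that held B cell/A20 UMIs; both values rest on 7 genes against 9. For the tissue macrophage genes other than C1q, fewer such cells cannot be told apart from lower expression, since the median went from -1.21 (-2.05 to -0.86) to -0.26 (-0.99 to 0.19) on 6 genes. Newly arrived monocytes in the TAK-981 tumour, or a change within resident cells, may underlie the rest, and neither was tested. Other cells rich in MHC class II, such as conventional dendritic cells, were not left out, so a different mix of subsets stays open. Nor does the monocyte list mark monocytes alone, as it was also higher in T cell-like cells (1.92).

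The third pattern is that interferon-list UMIs were concentrated in few B cell/A20-like cells of the TAK-981 library, a group picked by the outcome it is described by. The 17 cells richest in them (1%) held 13.5% of the list's UMIs, above the highest of 1000 deals of the same UMIs in proportion to depth (3.85%); in the vehicle library 20 cells held 6.87% against 3.67%. Droplets that also held a T cell or monocyte are argued against by 0.233 marker UMIs per 100 list UMIs, compared with 51.8 in the host class with fewer. Host B cells are argued against by Xist, found in 0.0% of the 17 cells (which allows up to 17.6%) and in 85.3% of host cells (76.5 to 91.7%). Of these cells 13 of 17, and 8 of the 20 in the vehicle library, lay in clusters 9 and 10, which both libraries hold. A stronger response of cells in that state is a candidate explanation that was not tested. A530040E14Rik, among the leading genes of both clusters, was also one in the cluster led by Usp18 when interferon genes entered the clustering. Genes that respond may thus have helped to set these clusters, so membership need not mark an earlier state. Without the 17 and the 20 cells the class median was 1.46.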
